A study of Mus musculus with 6 samples.

How the data were processed

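Polyadenylated RNA of fetal liver cells from C57BL/6J mouse embryos was measured by RNA sequencing in 6 libraries, 3 from wild-type (WT) embryos and 3 from embryos lacking the locus of miR-144 and miR-451 (KO). Each RNA preparation started from the same number of cells, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. WT libraries carry the numbers 1 to 3 and KO libraries 4 to 6, so no number pairs a WT with a KO library. A design text in the labels names HITS-CLIP, a method that maps protein-bound RNA sites, and such data were not analysed here.

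The authors deposited 2 tables of raw counts per gene symbol. The gene table lists 34542 genes, of which 12074 have no count in any library. The other table gives deposited exon counts and intron counts for 15543 genes, and its exon counts equal the counts of the gene table for all 15543. The exon counts are therefore the same measurement on fewer genes, not an independent one. STAR (an aligner) and HTSeq (a read counter) are named without versions in the submitters' processing notes, which also list the builds NCBIM37 and mm10. The build and gene models behind each table, the strand setting and how introns were defined are not given in the sources used here. Per the file headers and names, globin and mitochondrial genes had been taken out of the gene table, and 0 symbols starting with Hba, Hbb or mt- were found. Library sizes therefore leave out the globin transcripts. No summary line of unassigned reads was in the tables.

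The gene table holds 24659978 to 44700229 counts per library, and intron counts make up 16.9% to 23.4% of exon plus intron counts. Reads carry no molecular identifiers, so counting intervals cover counting error only. Pairs of libraries of the same group were compared by a chi-square of their counts over genes. The chi-square per degree of freedom ran from 16.7 to 157, so no pair agreed within sampling noise and each library was kept as 1 replicate.

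Counts were scaled by the trimmed mean of M values (TMM) and tested KO against WT with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood F test was used, with filterByExpr at its defaults (minimum count 10, minimum total 15) and an adjusted p threshold of 0.05 after Benjamini-Hochberg (BH) adjustment. Levels are CPM (counts relative to the TMM-scaled library size), as mean ± SD over 3 libraries. Standard errors of log2 changes were derived from the F statistic, and all tests are two-sided unless stated. The same test was run on gene counts, exon counts and intron counts. The exonic change was set against the intronic change in 1 fit over 12 columns (exon and intron counts of each library) with a term per sample, the tested term being the interaction of region with genotype. Exon and intron columns were scaled separately, so that comparison is relative to the median over genes. Intron counts stand for unspliced RNA, and part of them can come from retained introns or other transcripts in the interval.

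Gene symbols were matched to the mouse GENCODE annotation of build GRCm38: 29219 by the same symbol, 2174 by an older symbol and 3149 not at all. The tables' own build differs or is unknown, so coordinates printed are those of GRCm38 only. Seed sites were searched in the longest annotated 3' untranslated region (UTR) of each matched gene, and 20296 genes had one. Sites were the 8mer and 7mer-m8 matches of miR-451a (AACGGTT), miR-144-3p (ATACTGT) and miR-144-5p (TGATATC). Genes with a site were compared with the other tested genes that have a 3' UTR by camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, over 9 tests adjusted together. As a second comparison, median changes were set against 100 permuted words of the same bases per microRNA, where the smallest p is 0.0099. The words were not matched to the site by the number of genes that carry them. Shares of called genes were compared by Fisher's exact test, which treats genes as independent, and with the shares for the permuted words.

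Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 tested members were tested by camera in the same way, with BH adjustment over the 27 lists, and again with the correlation estimated from the data. The count of called members is given over all tested genes and also adjusted over the list alone. Named genes are the microRNA genes of the deleted locus, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 5 CPM and no overlap between groups, and 6 fixed genes (Ywhaz, Cab39, Foxo3, Cat, Gpx1 and Nfe2l2). Up to 4 called members per list, or the 2 most highly expressed where none was called, were named too. Some genes that the rule takes are not reported here. Gene models without a gene name were passed over, 6 among the decreases and 0 among the increases. The rule also covers genes whose exonic and intronic changes differed past the threshold, and 0 genes met it.

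Alternatives were size factors by the median ratio (RLE) in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a minimum mean of 1 CPM, and each library left out in turn. For the exon against intron comparison they were exon scaling of the intron counts, no sample term, a DESeq2 interaction and at least 20 intron reads in the mean. For sites they were 8mers only, the shortest 3' UTR, and exon counts. A hepatocyte marker level as a covariate, and leaving out both libraries with the highest such level, were added after the data were seen.

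The steps were tested on simulated counts drawn from these libraries' means and sizes with 200 changed genes. In the gene fit (15105 genes) 5.97% of genes changed 1.5-fold were called, 26.9% of those changed 2-fold and 68.2% of those changed 4-fold. In the intron fit (11803 genes) the shares were 0%, 23.9% and 83.3%. In the exon against intron fit (10963 genes) they were 0%, 6.06% and 64.6%. Most simulated changes of 2-fold or less were missed in all 3 fits. False calls were 5 of 72 calls in the gene fit, 2 of 73 in the intron fit and 7 of 53 in the exon against intron fit. Genes were drawn independently, as were the exon and intron counts of a library, so the simulation holds no structure that genes of a library share.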

Results

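RNA sequencing libraries of fetal liver cells were compared between 3 wild-type (WT) embryo samples and 3 samples lacking the locus of miR-144 and miR-451 (KO). Both microRNAs are abundant in maturing red cells, and they lower messenger RNAs that carry matching sites in their 3' untranslated regions (UTRs). The fetal liver is the main site of red cell formation in the embryo, and it also holds hepatocytes, macrophages and other blood cells. The comparison asks which transcripts differ when the locus is absent. Counts assigned to genes totalled 36082084, 34839659 and 24659978 in WT replicates 1, 2 and 3, and 44700229, 41021313 and 40392139 in KO replicates 4, 5 and 6. Introns took 16.9% to 23.4% of exonic plus intronic counts. The labels do not say whether a library came from a single embryo or a pool, so p-values measure the spread between these samples only. Hepatocyte content varied within both groups. The mean log2 level (CPM, normalised counts scaled to library size) of 20 hepatocyte markers was 8.01, 9.96 and 7.24 in WT replicates 1 to 3 and 7.83, 8.52 and 9.63 in KO replicates 4 to 6, with WT replicate 2 and KO replicate 6 the highest.

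The deleted microRNA genes were nearly absent from every KO library, as the labels state. Mir144 had 51, 47 and 29 counts in WT replicates 1 to 3 and 1, 1 and 0 counts in KO replicates 4 to 6. Per sequenced count, the KO level was 1.19% of WT (95% exact interval 0.143% to 4.40%, counting error only). Mir451 had 323, 446 and 418 counts in WT and 3, 2 and 4 counts in KO, a KO level of 0.575% of WT (0.262% to 1.09%). In the GRCm38 annotation Mir144 lies on chromosome 11 at 78073005 to 78073070 and Mir451a at 78073170 to 78073241, both as microRNA genes on the plus strand. Mir451b is annotated on the opposite strand over the same positions as Mir451a, and reads of the pair cannot be told apart without strand.

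Among called genes with a mean of at least 5 CPM, the largest increase in KO livers was in Chga, which encodes chromogranin A of neuroendocrine secretory granules. It went from 3.51 ± 0.616 CPM in WT to 115 ± 19.3 CPM in KO (SD, n = 3 each), a log2 change of 5.04 (SE 0.20). Its adjusted p was 8.1e-04 by edgeR's quasi-likelihood test with BH adjustment, as for all adjusted p-values of single genes here. Tac2, the tachykinin neurokinin B precursor, rose from 10.8 ± 0.382 to 51.9 ± 5.07 CPM (log2 change 2.26, SE 0.11, adjusted p = 0.00133, edgeR). Csf2rb2, the mouse interleukin-3 receptor beta subunit, rose from 12.9 ± 2.47 to 47.6 ± 3.88 CPM (1.88, SE 0.16, adjusted p = 0.00830, edgeR). The other large increases among called genes of that level were Rundc3a (log2 change 3.77), the ciliary protein gene Dzip1 (2.41), the chloride channel gene Ano1 (2.08) and Bex4 (1.84). Next came the choline transporter-like gene Slc44a5 (1.69), the linker histone gene Hist1h1c (1.60), the kinase signalling inhibitor Spry1 (1.52), the arginine deiminase gene Padi2 (1.31) and the butyrophilin gene Btn1a1 (1.29).

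Apart from the deleted genes and gene models without a gene name, the largest decrease among called genes with a mean of at least 5 CPM was in Socs3, a feedback inhibitor of cytokine receptor signalling, which fell from 25.9 ± 3.47 CPM in WT to 5.77 ± 0.634 CPM in KO (log2 change -2.16, SE 0.15, adjusted p = 0.00562, edgeR, n = 3 each). Xpo7, a nuclear export receptor abundant in maturing red cells, fell from 1939 ± 281 to 729 ± 111 CPM (-1.41, SE 0.17, adjusted p = 0.0180, edgeR). Mxd3, a partner of MAX, fell from 48.1 ± 1.69 to 16.0 ± 0.538 CPM (-1.59, SE 0.08, adjusted p = 0.00133, edgeR). The cyclin-dependent kinase inhibitor Cdkn2c (-1.39), the insulin-responsive glucose transporter Slc2a4 (-1.43) and the carnitine transporter Slc22a21 (-1.36) fell as well. So did the interferon-linked exonuclease gene Isg20 (-1.35), together with Snx22 (-1.98), Cdkl1 (-1.56), the translational repressor Nanos1 (-1.36) and the class I-like histocompatibility gene H2-T24 (-1.35). Several of these are uncertain as single genes. Snx22 overlaps Ppib and Mxd3 overlaps Prelid1 on the opposite strand, Xpo7 overlaps Npm2 and Dok2, and Csf2rb2, Hist1h1c and H2-T24 have closely related copies.

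**Figure D1:**
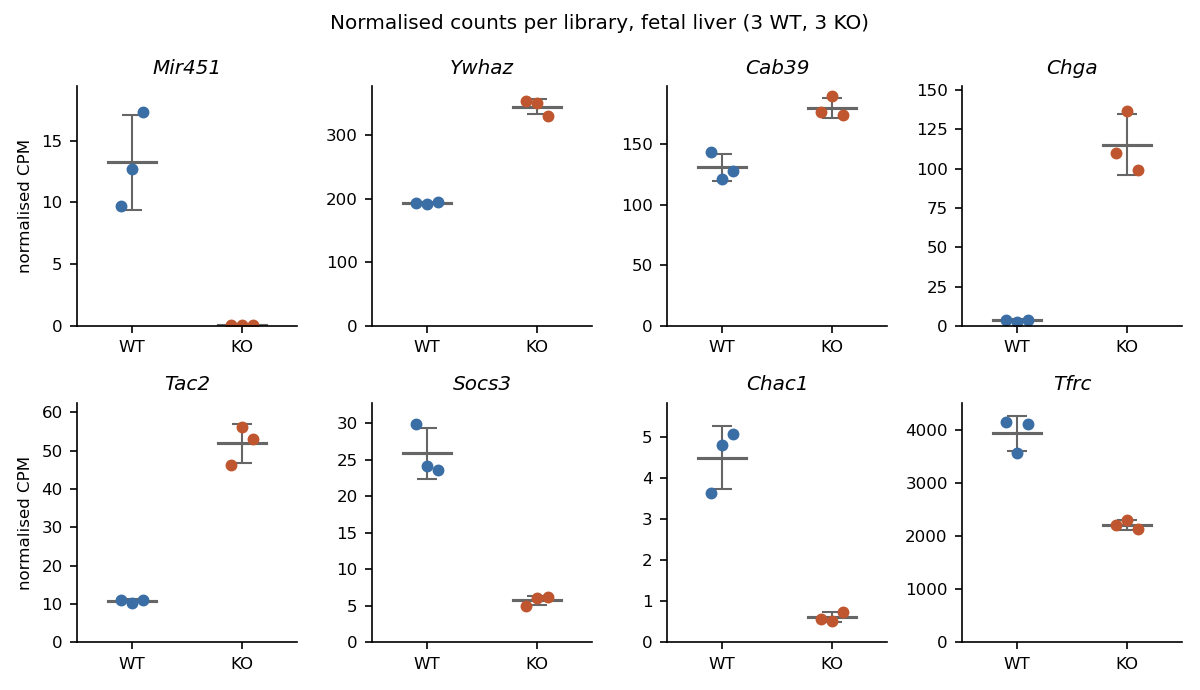
Normalised CPM of 8 genes in each of the 6 libraries, with points for libraries, a bar for the group mean and whiskers of 1 SD (n = 3 per group). Mir451 was nearly absent in KO, Ywhaz, Cab39, Chga and Tac2 were higher in every KO library than in every WT library, and Socs3, Chac1 and Tfrc were lower.

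In total 276 genes were higher and 219 lower in KO among 15105 tested (edgeR's quasi-likelihood test, adjusted p under 0.05), and 41 and 89 of them differed by more than 2-fold. Among all tested genes the groups did not overlap for 22.7%, against 10% by chance for 3 against 3. DESeq2 called 655 higher and 652 lower. The count rested on the number and choice of libraries. It was 6 and 8 without WT replicate 1, 6 and 9 without WT replicate 3, 14 and 12 without KO replicate 4, 5 and 7 without KO replicate 5 and 54 and 44 without KO replicate 6, but 483 and 1012 without WT replicate 2. Each of the 495 genes kept its sign and an unadjusted p under 0.05 by edgeR in all 6 of these fits. All 495 had no overlap between groups, and each fit reuses most of the libraries that selected them. That outcome was therefore largely set by the selection and is no test of stability. Of the 49 named genes past the threshold, Chga, Dzip1, Tac2, Mxd3 and Mir451 stayed past it in all 6. The others lost the call in at least 1: the number that kept it was 8 without WT replicate 1, 49 without WT replicate 2, 9 without WT replicate 3, 12 without KO replicate 4, 6 without KO replicate 5 and 23 without KO replicate 6.

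Of 14 tested messenger RNAs reported elsewhere as miR-451 targets, 4 rose. Ywhaz, which encodes the adaptor 14-3-3 zeta, went from 193 ± 1.32 to 345 ± 12.5 CPM (log2 change 0.84, SE 0.07, adjusted p = 0.00830, edgeR, n = 3 each). Cab39, the scaffold protein of the LKB1 kinase complex, went from 131 ± 11.3 to 180 ± 8.30 CPM (0.46, SE 0.09, adjusted p = 0.0481, edgeR), but its adjusted p was 0.0557 by limma-voom and 0.0526 without the filter on low counts. Vapa, a membrane contact protein of the endoplasmic reticulum, rose by 0.90 and the endosomal GTPase Rab14 by 0.47. Ywhaz and Cab39 have a miR-451a seed site in the searched 3' UTR, whereas Vapa and Rab14 have none. The other 10 did not pass and 0 fell, with a log2 change below 0 in 6 of the 14, including Il6ra (-0.33), Myc (-0.08) and Gata2 (-0.35). By DESeq2 5 rose and 0 fell, and 2 members were lower at an unadjusted p under 0.05. Adjusted over the list alone, 5 rose. The list was higher by camera (median log2 change 0.05, adjusted p = 0.00632; adjusted p = 0.491 with an estimated correlation).

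Of 13 tested miR-144 targets from earlier reports, Rab14 was the 1 that rose, with 2 adjusted over the list alone and 12 not past the threshold. Rab14 has no miR-144-3p or miR-144-5p site in the searched 3' UTR. Nfe2l2, the oxidative stress regulator NRF2, measured 120 ± 9.99 CPM in WT and 140 ± 11.1 in KO (log2 change 0.22, adjusted p = 0.321, edgeR, n = 3 each). The list was higher by camera (adjusted p = 0.0330; adjusted p = 0.491 with an estimated correlation). Its adjusted p was 0.0827 without WT replicate 3, 0.0501 without KO replicate 5 and 0.0684 with the hepatocyte marker level as a covariate. Among the 7 genes of the 14-3-3 family Ywhaz was the 1 that rose, and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.237). Of 24 genes of the LKB1, AMPK and mTORC1 network, Cab39 and Eif4ebp2, a translational repressor controlled by mTORC1, rose (0.46 and 0.61). Adjusted over the list alone 4 were higher and 1 lower, and the median (-0.05) and mean (-0.0027) had the opposite sign to the test, which did not pass (up, camera adjusted p = 0.565).

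Genes carrying a miR-451a seed site in the 3' UTR were shifted upward. Among 262 such genes the median log2 change was 0.08, against -0.03 for the other 12802, and 59.9% against 45.2% were above 0 (camera adjusted p = 7.0e-07; adjusted p = 0.134 with an estimated correlation). The size of the shift depended on single libraries: the difference of medians was 0.11 with all 6, 0.27 without WT replicate 2, 0.06 without WT replicate 3, 0.16 without KO replicate 4 and 0.05 without KO replicate 6. It was 0.18 without both libraries of highest hepatocyte marker level and 0.22 with the shortest 3' UTRs, but 0.07 for 8mer sites alone (camera adjusted p = 0.00971). None of 100 permuted words gave as high a median (permutation p = 0.0099, the smallest 100 words allow), though the words were not matched by number of genes. Of the 262 genes, 30 rose (11.5%, against 1.79% of genes without the site; odds ratio 7.10, 95% interval 4.58 to 10.7, Fisher's exact p = 6.4e-15) and 0 fell by edgeR. DESeq2 called 52 higher and 4 lower, and 9 were lower at an unadjusted p under 0.05. Fisher's test treats genes as independent. Per permuted word a median of 2.27% and at most 5.64% of genes rose, beside the 11.5% for the site. Besides Ywhaz, Cab39, Bex4, Slc44a5 and Eif4ebp2, these 30 included Rac1, a GTPase of the actin cytoskeleton (165 ± 10.8 to 340 ± 14.4 CPM, log2 change 1.05), and Ybx1, an RNA-binding protein (478 ± 39.2 to 822 ± 75.2 CPM, 0.78), both singled out after their values were seen.

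Over all sites and all 6 libraries the shift for miR-144-3p was smaller, but whether the 2 shifts differ was not tested. The 1703 genes with a site had a median of 0.02 against -0.03 (camera adjusted p = 0.0480; adjusted p = 0.200 with an estimated correlation), and 0 of 100 permuted words reached it (permutation p = 0.0099). Of them 66 rose (3.88% against 1.70%, odds ratio 2.33, 95% interval 1.73 to 3.12, Fisher's exact p = 6.0e-08) and 20 fell (odds ratio 0.782, Fisher's exact p = 0.330). DESeq2 called 153 higher and 72 lower, and 245 were higher and 120 lower at an unadjusted p under 0.05 by edgeR. Fisher's test treats genes as independent here too. Per permuted word a median of 2.46% and at most 3.69% of genes rose, beside the 3.88% for the site. The camera call was lost without WT replicate 1, WT replicate 2, KO replicate 4, KO replicate 5 or KO replicate 6, with adjusted p of 0.0964, 0.191, 0.0560, 0.0655 and 0.107. For 8mer sites alone the difference of medians was 0.08, beside 0.05 for all sites, and 0.07 for 8mer sites of miR-451a. Without KO replicate 6 the difference over all sites was 0.05 for both microRNAs. The 760 genes with a site for miR-144-5p, the other strand of the hairpin, showed no shift past the threshold (camera adjusted p = 0.834, odds ratio for higher genes 0.995). Of the 259 higher genes with an annotated 3' UTR, 88 had a miR-451a or miR-144-3p site and 171 had neither.

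**Figure D2:**
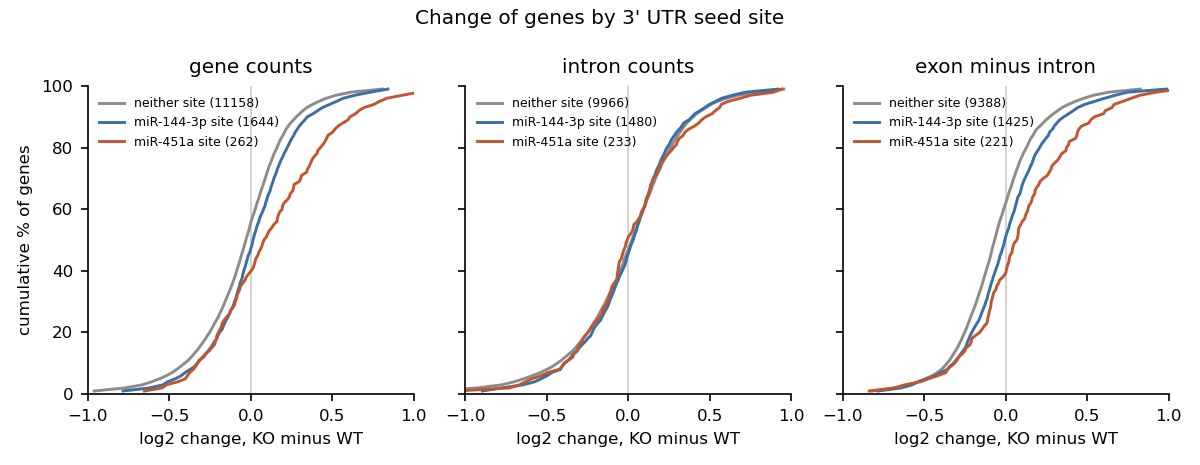
Cumulative percent of genes (vertical axis) against the log2 change, KO minus WT (horizontal axis, shown from -1 to 1), for gene counts, intron counts and the exonic minus intronic change. Lines stand for genes with a miR-451a site, genes with a miR-144-3p site and no miR-451a site, and genes with neither, with the number of genes in brackets. At the median the miR-451a line lies to the right for gene counts (0.08) and for exonic minus intronic change, and not for introns.

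Intron counts separated changes in mature RNA from changes in unspliced RNA. Introns of genes with a miR-451a site showed no shift past the threshold (233 genes, median -0.0071 against 0.02, camera adjusted p = 0.834), whereas their exonic minus intronic change was higher by 0.13 than that of other genes (221 genes, camera adjusted p = 9.0e-08; adjusted p = 0.0888 with an estimated correlation; 0 of 100 permuted words as high). That difference was 0.25 without WT replicate 2 and 0.20 without both libraries of highest hepatocyte marker level. The same difference for miR-144-3p was 0.06 over 1478 genes (camera adjusted p = 0.0274; adjusted p = 0.200 with an estimated correlation). Without WT replicates 1 or 2 or KO replicate 6 it lost the call, with adjusted p of 0.137, 0.223 and 0.128, and without both libraries of highest hepatocyte marker level it was 0.03. Introns of genes with a miR-144-3p site, and both intron measures for miR-144-5p, did not pass (camera adjusted p = 0.834 for each).

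For Ywhaz the exonic change exceeded the intronic change by 0.92 (SE 0.25, unadjusted p = 0.00684, adjusted p = 0.972, edgeR interaction), with introns at 127 ± 35.5 CPM in WT and 117 ± 19.1 in KO (n = 3 each). The intron counts of Chga rose from 4.04 ± 1.30 to 226 ± 29.4 CPM (log2 change 5.81, adjusted p = 2.2e-04, edgeR). Introns of Tac2 (2.22), Csf2rb2 (2.94), Dzip1 (2.28) and Rundc3a (2.02) rose too, and those of Socs3 (-2.13), Mxd3 (-1.70) and Snx22 (-2.03) fell.

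No single gene passed the test of exonic against intronic change. By edgeR's interaction test 0 of 11100 genes passed in either direction and the smallest adjusted p was 0.222, while 351 had an unadjusted p under 0.05, 184 of them with the exonic change higher. DESeq2 called 35 higher and 9 lower, edgeR without the sample term called 9 and 0, and without WT replicate 3 the counts were 48 and 124. In intron counts 28 genes were higher and 57 lower among 11803 tested. Of these 85, 77 were tested in gene counts, where 45 passed in the same direction. Some introns changed where the gene count did not pass. Il6ra introns fell from 187 ± 36.8 to 30.3 ± 2.81 CPM (log2 change -2.63, adjusted p = 0.00140, edgeR, n = 3 each) beside a gene change of -0.33, and Arl4a introns fell by 2.38 on the log2 scale beside -0.36. Ppib introns (-1.30) share positions with Snx22, and Il6ra overlaps Gm42809 on the opposite strand. Il6ra, Arl4a and Ppib were chosen after their values were seen. Of the 32 genes with an intron call that did not pass in gene counts, 15 overlap another gene. Over all intron calls the share was 37.6%, against 43.3% of the other tested genes. The intron counts also depended on single libraries: 6 and 17 without WT replicate 1, 4 and 6 without WT replicate 2, 27 and 121 without WT replicate 3, 5 and 7 without KO replicate 4, 4 and 9 without KO replicate 5, and 6 and 16 without KO replicate 6. The exon table gave 191 higher and 137 lower of 12032, all 328 among the 495 genes of the gene table. Leaving out WT replicate 1, 2 or 3 or KO replicate 4, 5 or 6 gave 2, 383, 5, 10, 2 and 21 higher and 0, 887, 2, 5, 1 and 14 lower, and at WT replicate 1 561 were lower at an unadjusted p under 0.05.

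Lists of red cell membrane genes, erythroid transcription factors, S phase and G2/M genes were lower by camera, and each lost the call with an estimated correlation (adjusted p = 0.870 for each). The transferrin receptor Tfrc fell from 3933 ± 326 to 2211 ± 86.8 CPM (log2 change -0.83, SE 0.14, adjusted p = 0.0336, edgeR, n = 3 each), and was the 1 of 22 heme synthesis and iron supply genes to pass. It alone passed adjusted over the list alone too, and the list did not (camera adjusted p = 0.0839). The list passed as lower without WT replicate 2 (adjusted p = 4.3e-04), without KO replicate 5 (0.0110) and without both libraries of highest hepatocyte marker level (0.00569). Among 27 red cell membrane and surface genes the blood group adhesion protein gene Icam4 (-0.81) and the membrane skeleton gene Epb4.2 (-0.72) fell, 25 did not pass and 0 rose. At an unadjusted p under 0.05 by edgeR 13 were lower and 0 higher, and DESeq2 called 11 lower and 0 higher. Adjusted over the list alone 10 fell (camera adjusted p = 5.7e-07; adjusted p = 0.870 with an estimated correlation). Among 18 erythroid transcription factors the repressor Klf3 (-0.94) and the cell cycle regulator E2f2 (-0.97) fell, and 4 adjusted over the list alone (camera adjusted p = 4.6e-05; adjusted p = 0.870 with an estimated correlation). Foxo3 measured 498 ± 61.9 CPM in WT and 479 ± 30.4 in KO (-0.06, adjusted p = 0.940, edgeR).

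Of 24 G2/M phase genes the cytokinesis gene Anln (-0.80), the ubiquitin-conjugating enzyme gene Ube2c (-0.73) and the kinetochore gene Cenpf (-0.80) fell. Adjusted over the list alone 14 fell and 1 rose (camera adjusted p = 1.4e-09; adjusted p = 0.870 with an estimated correlation). Of 24 S phase genes Rrm2, a ribonucleotide reductase subunit, fell (-0.97), 1 adjusted over the list alone, and 22 of 24 had a log2 change below 0 (camera adjusted p = 6.7e-05; adjusted p = 0.870 with an estimated correlation). Of 20 genes of ATF4 and the integrated stress response 4 fell, with 7 adjusted over the list alone (camera adjusted p = 2.3e-05; adjusted p = 0.491 with an estimated correlation). They were Chac1, a glutathione-degrading enzyme (4.49 ± 0.765 to 0.617 ± 0.119 CPM, log2 change -2.86), Trib3 (-1.68), the phosphatase subunit Ppp1r15a (681 ± 78.0 to 304 ± 28.3 CPM, -1.16) and Atf4 itself (-0.62). Calls of Trib3 (limma-voom), Tfrc, Epb4.2 and Atf4 (no filter on low counts) were lost, with adjusted p of 0.0547, 0.0599, 0.0736 and 0.0708.

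Within each group, S phase, G2/M, erythroid factor and red cell membrane genes were lowest in the library of highest hepatocyte marker level. In WT replicate 2 the median S phase gene lay at -0.17 and the median erythroid factor at -0.13 relative to the mean of all 6 libraries. WT replicates 1 and 3 lay at 0.26 and 0.25, and at 0.26 and 0.22. In KO replicate 6 the values were -0.28 and -0.25, the lowest of the KO libraries. Red cell membrane genes lay at -0.07 in WT replicate 2 against 0.38 and 0.20, and G2/M genes at -0.04 against 0.33 and 0.26. The hepatocyte level was not followed throughout. G2/M genes in WT replicate 2 lay above KO replicates 4, 5 and 6 (-0.16, -0.13 and -0.24). KO replicate 4, of lower marker level than KO replicate 5, lay lower for red cell membrane genes (-0.16 against -0.06). In contrast, S phase genes and erythroid factors in WT replicate 2 lay below KO replicates 4 and 5 (0.0009 and -0.07, and -0.08 and -0.06).

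**Figure D3:**
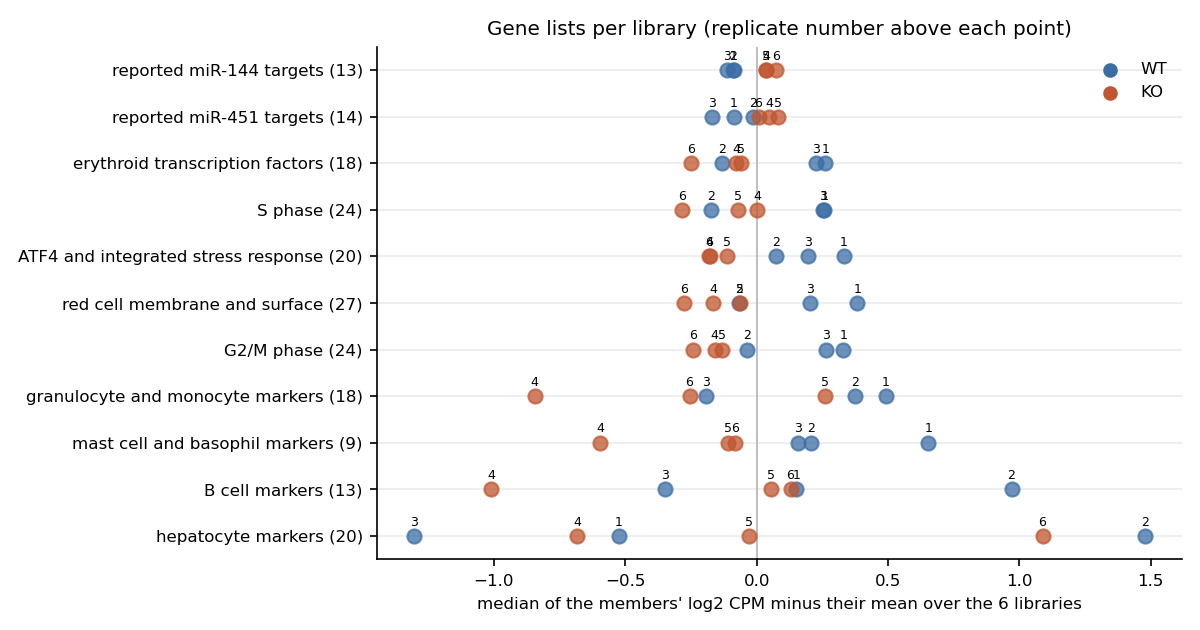
Median over list members of log2 CPM minus the member's mean over the 6 libraries (horizontal axis), for the 10 lists past the camera threshold and hepatocyte markers, with the number of tested members in brackets and the replicate number above each point. For hepatocyte markers WT replicate 2 (1.48) and KO replicate 6 (1.09) stand apart from the other 4 libraries.

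Lists of antioxidant and clearance pathways did not pass with all 6 libraries. FOXO3 and antioxidant genes passed as lower without KO replicate 5 (camera adjusted p = 0.0393), and autophagy and mitophagy genes as higher without WT replicate 1 (0.0347). In the list of FOXO3 and antioxidant genes 0 of 25 passed by edgeR (1 higher and 2 lower at an unadjusted p under 0.05; DESeq2 called 1 and 2), 0 adjusted over the list alone (camera adjusted p = 0.237). Catalase (Cat) measured 672 ± 91.9 and 547 ± 74.6 CPM (log2 change -0.30, adjusted p = 0.411), glutathione peroxidase (Gpx1) 3419 ± 494 and 2379 ± 274 CPM (-0.52, adjusted p = 0.196, both by edgeR, n = 3 each), and Prdx2 -0.20. Of 22 NRF2 targets 0 passed, also over the list alone (1 higher and 1 lower at an unadjusted p under 0.05 and by DESeq2), with Fth1 at -0.05 and Ftl1 at 0.11. The NRF2 median (0.04), mean (-0.0084) and test (up, camera adjusted p = 0.505) differed in sign. Of 24 autophagy and mitophagy genes 0 passed, also over the list alone (3 higher and 1 lower unadjusted; 1 higher by DESeq2), with Bnip3l at -0.28 and Ulk1 at 0.07 (camera adjusted p = 0.340). Of 20 p53 targets 0 passed, also over the list alone (3 and 4 unadjusted; 1 lower by DESeq2), with Btg2 at -0.37 and Ccng1 at 0.25 (camera adjusted p = 0.505). Limma-voom called 0 in each of these 4 lists. Among 14 genes of the small RNA machinery Tnrc6c, a partner of Argonaute proteins, fell (-0.37), a call lost without the filter on low counts (adjusted p = 0.122). Adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.540).

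Marker lists of mast cells, of granulocytes and monocytes and of B cells were lower by camera, and those of mast cells and B cells lost the call without single libraries. Among 9 mast cell and basophil markers the interleukin-33 receptor gene Il1rl1 fell from 65.6 ± 5.76 to 33.3 ± 3.50 CPM (log2 change -0.98, adjusted p = 0.0147, edgeR, n = 3 each), with 2 adjusted over the list alone (camera adjusted p = 0.00435; adjusted p = 0.870 with an estimated correlation; camera adjusted p = 0.0550 without KO replicate 4). All 18 granulocyte and monocyte markers had a log2 change below 0 and 0 passed by edgeR, also over the list alone (2 lower unadjusted; 1 by DESeq2, 0 by limma-voom), with S100a9 at -0.71 and Mpo at -0.24 (camera adjusted p = 9.3e-05; adjusted p = 0.870 with an estimated correlation). All 13 B cell markers lay below 0 and 0 passed by any of the 3 tools, at an unadjusted p under 0.05 or over the list alone, with Rag1 at -0.57 and Cd79b at -0.40. The B cell list passed camera (adjusted p = 0.0397; adjusted p = 0.933 with an estimated correlation) but not without WT replicate 2 (0.876) or KO replicate 4 (0.485). KO replicate 4 was lowest for all 3 lists (-0.60, -0.84 and -1.01).

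Early progenitor genes did not pass: 0 of 18 by edgeR, DESeq2, limma-voom or over the list alone, 3 lower at an unadjusted p under 0.05, with Kit at -0.10 and Myb at -0.39 (camera adjusted p = 0.332). Of 19 macrophage markers Dnase2a, the lysosomal nuclease gene, fell (-0.72), 1 also over the list alone (camera adjusted p = 0.340); it overlaps Mast1 on the opposite strand. The macrophage list passed as lower without WT replicate 3 (adjusted p = 0.00243) and with the hepatocyte covariate (0.0338). Interferon response genes gave 0 of 20 by edgeR (1 higher and 2 lower unadjusted; 2 lower by DESeq2 and 1 by limma-voom; 1 lower over the list alone), with Rsad2 at -1.31 (camera adjusted p = 0.540). That list passed as lower without KO replicate 6 (adjusted p = 0.00707), where the list's median lay 0.47 above the mean of all 6 libraries, and without both libraries of highest hepatocyte marker level (0.0489). Hepatocyte, megakaryocyte, endothelial, stellate and mesenchymal, and sex-linked lists gave 0 calls by edgeR, DESeq2 and limma-voom and over the list alone, and 0, 0, 0, 1 and 0 genes at an unadjusted p under 0.05. Their camera adjusted p were 0.505, 0.938, 0.237, 0.938 and 0.849. Most expressed among them were Alb (-0.09) and Afp (0.11), Thbs1 (-0.19) and Itgb3 (-0.16), Stab2 (0.12) and Stab1 (0.08), Col3a1 (0.02) and Col14a1 (-0.02), and Xist (0.26) and Ddx3y (-0.26). The hepatocyte median and mean (-0.03 and -0.02) were opposite in sign to its test, and the stellate median (0.02) to its mean (-0.01) and test. Endothelial markers had WT replicate 2 (0.84) and KO replicate 6 (0.95) as the highest libraries, as for hepatocyte markers. Both lists passed as higher without WT replicate 2 (adjusted p = 5.0e-04 and 3.8e-05), and endothelial markers also without KO replicate 4 (0.0485) or KO replicate 5 (0.0393). Of 16 stress and handling genes, which respond to tissue processing, the phosphatase gene Dusp1 (-0.95) and Ier3 (-1.26) fell, with 3 over the list alone. The list's median (0.16) and mean (0.21) were opposite in sign to its test (down, camera adjusted p = 0.765), and Ier3 lost its call by limma-voom (adjusted p = 0.0579).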

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

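The hepatocyte covariate, and leaving out both libraries of highest hepatocyte marker level (WT replicate 2 and KO replicate 6), were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. Counts below are higher and lower in KO, and uncalled results were taken to have no direction, under which none reversed. With 1 library left out, fewer samples enter the fit, and the covariate uses a degree of freedom while it removes spread; for the other alternatives the cause was not tested. In gene counts (276 and 219) RLE, limma-voom, no filter and a 1 CPM minimum stayed within 1.5 times. DESeq2 gave 655 and 652, leaving out 1 library 5 to 483 and 7 to 1012, leaving out both 580 and 838, and the covariate 1283 and 1296. In exon counts (191 and 137) DESeq2 gave 518 and 497, no filter 256 lower, 1 library out 2 to 383 and 0 to 887, both out 473 and 745, and the covariate 1085 and 1122. In intron counts (28 and 57) DESeq2 gave 123 and 217, 1 library out 4 to 27 and 6 to 121, both out 1 and 0 by edgeR, and the covariate 5 and 9. For exonic against intronic change (0 and 0) no sample term gave 9 and 0, DESeq2 35 and 9, and 1 library out 0 to 48 and 0 to 124. Scaling intron counts with the exon factors moved the median exonic minus intronic change of all genes by 0.14, and RLE moved the higher share in gene counts by 0.46 percentage points.

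Of 9 seed tests 4 passed, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Then the adjusted p was 0.134 (miR-451a) and 0.200 (miR-144-3p) in gene counts and 0.0888 and 0.200 for exonic minus intronic change. With 1 library out 2 to 4 passed, and with both out 2. For miR-451a the adjusted p with 1 library out ran from 7.8e-08 to 1.6e-04 in gene counts and from 5.4e-07 to 0.0324 for exonic minus intronic change. For miR-144-3p it ran from 0.0480 to 0.191 and from 0.0127 to 0.223; with both out it was 0.170 and 0.513, and 0.0598 in gene counts with the covariate. Of the 27 lists 10 passed, and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05 (smallest p 0.0510); limma's fry, which tests for change and not against other genes, gave 6 lists an unadjusted and 3 an adjusted p under 0.05. With 1 library out 9 to 12 passed. Hepatocyte markers passed as higher without WT replicate 2 (adjusted p = 3.8e-05) and with both libraries out (4.9e-04), and endothelial markers likewise (5.0e-04 and 4.9e-04). Of the 49 named genes past the threshold, all 49 kept their sign under every alternative that tested them, which their selection largely fixed. Of these, 42 stayed past the threshold in every planned fit of all 6 libraries that tested them. Mir144 lay below the 1 CPM minimum and was not tested there.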

Other observations

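The tests of hepatocyte content and of scaling, the test of DNA flanking the locus and both tests on Xist and Ddx3y were chosen only after the result was seen, as was the fit with a hepatocyte covariate. Most genes next to the deleted locus did not pass the test. Of the 10 tested neighbours on each side on chromosome 11, Eral1, which encodes a mitochondrial ribosome assembly factor and lies on the far side of Mir451, was the 1 that rose, from 18.4 ± 2.14 to 31.0 ± 2.83 CPM (log2 change 0.75, SE 0.13, adjusted p = 0.0347, edgeR, n = 3 each). Traf4, next to Eral1, had a log2 change of 0.43 (adjusted p = 0.137), and Flot2, on the other side, 0.28 (adjusted p = 0.129). In the receptor pair Csf2rb and Csf2rb2, introns of Csf2rb rose by 0.98 (adjusted p = 0.0485, edgeR) beside 2.94 for Csf2rb2. The gene count of Csf2rb had a log2 change of 0.30 (adjusted p = 0.266, edgeR). Whether the 2 changes differ was not tested, and the near-identical copies can share reads. These genes were singled out after their values were seen.

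The 113 tested members of the G2/M, S phase, red cell membrane, erythroid factor and ATF4 lists had a median log2 change of -0.29 (95% bootstrap interval -0.35 to -0.23). Camera had called these lists lower in the same data. The intervals given here resample genes as if independent, so they hold no spread between libraries. With the hepatocyte marker level as a covariate the median was -0.25 (-0.31 to -0.18), and 52 members were called lower and 4 higher, against 12 and 0 without it. Calls over all tested genes grew as well, from 219 lower and 276 higher to 1296 and 1283. Removing the trend of change with GC content left -0.30 (-0.34 to -0.22). The GC trend moved 95% of all tested genes by at most 0.06, which argues against GC content as the whole source. Hepatocyte content as the source would have put the covariate median above -0.1, a value set after the data were seen. The whole covariate interval lay below -0.1, though it holds no spread between libraries. For these members the covariate fit argues against hepatocyte content as the whole source. The covariate interval reaches above -0.2, the bound set for excluding hepatocyte content, so a part stays open. Hepatocyte markers themselves had a median change of -0.03 with all 6 libraries but 1.17 without WT replicate 2, so their change does not decide the question. A scaling factor moves all genes of a library alike. The members' median minus that of the other tested genes was -0.26 (-0.32 to -0.20, below a bound of -0.1 set after the values were seen). Camera compares members with other genes and had called these lists lower, so the selection largely set that value. It therefore cannot decide on scaling. The embryos' stage and litter are not stated and cannot be told apart from genotype: 3 of the 10 splits of the 6 libraries gave as large a median in size, the real one 0.289 and the highest other 0.310, that of WT replicates 1 and 3 with KO replicate 5 against the rest. A biological difference between the genotypes stays open as well, as untested.

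Of the genes that rose with neither a miR-451a nor a miR-144-3p site, 156 had testable introns, and their median intronic log2 change was 0.49 (95% bootstrap interval 0.38 to 0.60) beside 0.62 in gene counts. For the 83 that rose with a site it was 0.21 (0.10 to 0.30) beside 0.66, a difference with permutation p = 1.7e-04 (100000 draws). For the 28 with a miR-451a site it was 0.12 beside 0.69. The draws and intervals treat genes as independent and hold no spread between libraries. A candidate explanation is that many increases without a site, Chga, Tac2 and Dzip1 among them, follow a change in unspliced RNA. Intron counts can also come from retained introns or other transcripts, so a change in transcription downstream of the locus was not tested. Another split of the libraries gave more intron calls than genotype did (440 against 85). DNA carried along beside the deleted locus would place such genes near it, but 2.34% of the 171 genes (Eral1, Plscr3, Unc119 and Vps53) lie within 10 Mb, against 2.28% of tested genes. Sites outside the 3' UTR, and sites of other types, stay open. Vapa and Rab14, reported targets without a site in the searched 3' UTR, rose with smaller intronic changes (0.10 and 0.14).

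Every library held both Xist, transcribed from the inactive X of females, and the Y-linked Ddx3y. Xist ran from 231 to 1165 CPM and Ddx3y from 30.1 to 92.9 CPM. Across the 6 libraries they went opposite ways (Pearson r = -0.953, exact permutation p = 0.00556, adjusted 0.0111; Spearman rho = -0.943, exact permutation p = 0.0167, adjusted 0.0167 over the 2 coefficients), and r was -0.918 without the 2 libraries farthest from the median of Xist. The lowest Ddx3y was 32.4% of the highest. Mir451 allows up to 1.09% of reads carried over from WT into KO libraries, but carry-over within a group was not measured and stays open. A candidate explanation is that each library pools embryos of both sexes, so that replicates may be pools rather than single embryos.

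The 6 libraries in groups of 3 make 10 splits, too few for a share under 0.05. In gene counts the real split gave 495 genes and the highest other 0 (1 of 10 splits as large), and in exon counts 328 and 0 (1 of 10). In intron counts it gave 85 and the highest other 440 (2 of 10), that of WT replicates 1 and 2 with KO replicate 4 against the rest. That points to a structure of the samples in unspliced RNA other than genotype. Xist was lower in WT replicates 1 and 2 and KO replicate 4 (231, 603 and 491 CPM) than in WT replicate 3 and KO replicates 5 and 6 (1165, 1016 and 884 CPM). Any link to the intron calls was not tested. For exonic against intronic change it gave 0 and 0 by edgeR (10 of 10). For the seed sets the camera p was 1.6e-07 against a smallest other of 1.1e-05 for miR-451a (1 of 10), and 0.0213 against 0.0266 for miR-144-3p (1 of 10). Further splits gave a camera p of 3.6e-04, 6.5e-04, 0.0155 and 0.0261 for miR-451a, and the rest 0.0597 to 0.741. A small camera p at the preset correlation was therefore not particular to the genotype split.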
